A study of Mus musculus with 44 samples.

How the data were processed

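The F4/80+ cells of the CD11b-enriched fraction of bone marrow, spleen and mammary tissue were compared from 1 deposited table of 15425 genes and 74 columns. The 44 columns whose names match the sample titles were used, 27 of KEP and 17 of NeuT mice, and the other 30 columns have no sample here and were not used. Mammary tissue was digested with collagenase and trypsin at 37 °C and spleen and marrow were not, per the labels' protocols. Total RNA was amplified and sequenced as 50 bp single-end reads, per the labels' protocols. CASAVA 1.8, Bowtie2 2.2.1, Partek 6.6, DESeq2 and the mm10 build are named without roles, per the submitters' processing notes.

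The deposited values are a normalized signal made by the authors, whose unit no label gives. Their pattern shows a read count divided by 1 factor per library, plus a constant that differs by gene and by model, with values below 1 set to 1 and 6 significant digits kept. The constants raise some genes and lower others, with 8724 above 0 and 5509 below in KEP and 9636 and 4172 in NeuT, so they were removed before any test. For each gene and model the constant was taken from the values themselves, where the values above it are whole multiples of a library's step. At the constants found, 99.97% of 352537 KEP values and 99.999% of 219025 NeuT values lay within 0.1 of a whole read. Constants were settled for 14233 genes in KEP, leaving 1192 of which 590 were at the lowest value in every library, and for 13808 in NeuT, leaving 1617 of which 589 were. In simulated tables of 3000 genes per model all 2614 and 2647 settled genes came back right. Of the 15425 genes 12134 had a value in all 44 libraries, 448 were at 1 in all 44 and 1183 had no usable group.

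A value at the lowest level means fewer reads than a limit that the constant sets. Where the limit was 10 or less it was replaced by 0.5 of the limit, called "at the floor" in the text, and otherwise the group was left out for that gene. Values are the recovered reads over the library's factor, called normalized reads, and keep the authors' scaling. The table's unit differs from what the plan assumed, so the planned log2 of the deposited values became log2 of normalized reads plus 1, and the deposited values stayed as an alternative.

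Genes were tested with limma (trend, all 44 libraries in 1 fit with a mean per group), and p-values were adjusted by Benjamini-Hochberg within a comparison, with 0.05 as the limit. A gene was tested where at least 3 of the libraries reached 10. Interactions tested the difference of the tumor changes of KEP and NeuT in a tissue. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated per list. Lists with fewer than 5 tested genes were only counted. Beside each count of list genes stands the count adjusted over the list alone.

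Other settings were pseudocounts of 0.1 and 10, no filter, a filter of 50, quantile normalization, upper quartile scaling, a fit of the compared groups alone and leaving out each library in turn. Added after the values were seen were the values as deposited, floored values at their upper limit, genes with values in all libraries, voom weights on the recovered reads, and a term for a break in the KEP library numbers. That term was the difference of PRE spleen replicate 3 from replicates 1 and 2, taken off every KEP comparison across the break in the same limma fit. Genes whose constant could not be settled were left out of the tests.

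The lists were macrophage identity, inflammatory monocyte, resident macrophage, tumor-macrophage literature genes, MHC class II and co-stimulation, interferon-stimulated genes, glycolysis and hypoxia, cell cycle, lysosome, lipid uptake and efflux, cholesterol synthesis, inflammatory cytokines and NF-kB targets, matrix proteases and inhibitors, immune checkpoint and suppression, iron and heme handling, and immediate-early and dissociation response. The marker lists of other cells were eosinophil, neutrophil, T and NK cell, B cell and plasma cell, dendritic cell, erythroid, mammary epithelium, fibroblast, endothelium, adipocyte and mast cell. They were written from general knowledge before the data were examined, as were the comparisons, most of the other settings tried and the rule for naming genes. That rule named the 8 largest rises and 6 largest falls in TUM against WT and PRE against WT mammary cells, and 4 of each elsewhere. They had to pass the adjusted test, with groups that did not overlap, a mean of at least 100 in the higher group and a symbol that is not a predicted gene, clone or small RNA. The interaction named 6 in each direction. Also named were up to 4 members of each list, the sort and receptor genes Adgre1, Itgam and Csf1r, and Cdh1, Trp53 and Erbb2. Reads of close relatives, such as the Cd209 family and histone genes, can be counted for each other, and this was not tested.

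Recovered reads per library ranged from 2972397 to 13790175 in KEP and from 999438 to 3394300 in NeuT, so that 1 read stood for 0.217 to 1.14 normalized reads in KEP and 0.88 to 2.79 in NeuT. The ribosomal Rn45s made up 5.59% to 15.3% of the deposited sum in KEP and up to 17.0% in NeuT. No 2 libraries of a group were copies, the lowest chi-square per degree of freedom being 2.35 over genes with at least 20 reads. KEP TUM mammary replicate 1 stood apart from replicates 2 and 3 (68.9 and 61.1, against 11.7 between those), with Lyz2 at 0.854% of reads against 2.77% and 3.07%, and was kept. The replicates were numbered in the order of the labels, which is that of the library numbers in the titles. After the values were seen, genes of KEP were checked for a break in that order, between PRE spleen replicates 2 and 3, by asking in each tissue whether every library before it lay apart from every library after it. WT mice are described only as matched in age and sex, per the labels' protocols, and 1 WT group per tissue served PRE and TUM. The limma test was checked on 10730 simulated genes, 100 changed 2-fold and 100 changed 4-fold, for each model. The real mammary tumor tests called far more genes, so the shares found, given below, need not hold for them. Symbols were those of the table, 14780 of which were found in the table of gene names. Software was R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.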

Results

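Adgre1, the gene of the F4/80 antigen used for sorting, was highest in the mammary groups. It stood at 1459 ± 162 normalized reads (mean ± SD, n = 3) in KEP wild-type mammary gland, 434 ± 246 in spleen and 237 ± 25.4 in bone marrow. In the NeuT strain it stood at 1735 ± 275, 369 ± 55.3 and 165 ± 6.92. The F4/80+ cells came from 44 libraries in 15 groups, each of 3 samples except NeuT tumor-bearing spleen with 2. KEP mice (FVB) lack Cdh1 and Trp53 in K14-expressing epithelium and were sampled as wild type (WT), with early lesions at 4 months (PRE) and with tumors at 8 months (TUM). NeuT mice (Balb/c) carry a rat Neu transgene and were sampled as WT and as TUM at 4 months. Log2 fold changes are given ± SE, and p-values come from limma with Benjamini-Hochberg adjustment. They measure the spread between these samples, because the labels do not say that replicates are separate animals. Model, strain and library series ran together, so no difference between KEP and NeuT can be assigned to any 1 of them. KEP TUM mice, at 8 months, were also older than KEP PRE and NeuT TUM mice, so age is not separated in those comparisons either. In KEP 1 WT group per tissue, of an age given only as matched, serves PRE and TUM. The comparisons and lists of genes were chosen before the data were examined.

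Cdh1, the gene of E-cadherin deleted in KEP epithelium, lay between 0 and 282 normalized reads over all 44 samples. In KEP mammary tissue it stood at 91.2 ± 35.9 in WT, 139.7 ± 124 in PRE and 40.1 ± 30.8 in TUM (TUM against WT -1.34 ± 0.90, adjusted p = 0.32, n = 3). The tumor suppressor gene Trp53 lay between 163 and 357 in all samples, with 199.9 ± 40.5 in KEP WT mammary gland and 272 ± 36.6 in TUM (0.45 ± 0.19, adjusted p = 0.084). Mouse Erbb2 is the counterpart of the rat transgene. Whether reads of the transgene were counted for it was not tested, so it is no check of the NeuT labels. Erbb2 lay between 0 and 47.2. It rose in NeuT TUM mammary cells from 4.49 ± 4.81 to 27.4 ± 19.4 (2.42 ± 0.66, adjusted p = 0.0052), and fell in KEP TUM from 13.7 ± 3.3 to 0.13 ± 0.225 (-3.69 ± 0.66, adjusted p = 5.8e-05). No deletion or transgene was checked from these values, and every bone marrow or spleen group held Cdh1 below 10 and Erbb2 below 6 on average. In NeuT, Cdh1 went from 13.6 ± 12.1 to 63.8 ± 31.6 (2.30 ± 0.90, adjusted p = 0.053) and Trp53 from 215 ± 36.2 to 300.2 ± 40.5 (0.48 ± 0.19, adjusted p = 0.053).

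In mammary macrophages of KEP tumor-bearing mice Pdpn, which encodes a membrane glycoprotein that binds CLEC-2, rose from 6.93 ± 4.66 to 793 ± 656 (6.28 ± 0.68, adjusted p = 8.9e-09, n = 3 each). Arg1, whose product breaks down arginine, rose from 17.8 ± 4.59 to 1296 ± 899 (5.92 ± 0.75, adjusted p = 2.1e-07). Tnfrsf9, a co-stimulatory receptor gene, rose from 1.59 ± 1.38 to 101 ± 67.2 (5.05 ± 0.62, adjusted p = 1.0e-07), and Arhgap24, a regulator of Rac, from 6.29 ± 5.07 to 164 ± 10.4 (4.71 ± 0.55, adjusted p = 3.6e-08). Col14a1, a fibril-associated collagen gene, rose from 29.9 ± 19.9 to 674 ± 449.6 (4.55 ± 0.75, adjusted p = 1.7e-05) and Spp1, the gene of osteopontin, from 149 ± 92 to 3184 ± 1925 (4.31 ± 0.43, adjusted p = 1.4e-09). Tmem119, best known as a marker of microglia, went from 34.2 ± 30.9 to 322 ± 90.9 (4.06 ± 0.65, adjusted p = 1.1e-05). Htra3, a secreted protease gene at the floor in WT, reached 199 ± 90.2 (adjusted p = 4.1e-08).

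Among the largest falls in KEP tumors Retnla, a secreted protein gene of alternatively activated macrophages, went from 16921 ± 1759.6 to 76.6 ± 50.6 (-7.95 ± 0.50, adjusted p = 2.4e-14, n = 3 each). The lectin genes Cd209b, Cd209d and Cd209g fell by 7.80 ± 0.86 (adjusted p = 1.4e-08), 7.44 ± 0.71 (6.9e-10) and 7.05 ± 0.53 (2.8e-10), from 2663 ± 654, 2595 ± 494 and 1555 ± 85.5. C1qtnf1, a secreted C1q-related gene, fell from 897 ± 37.5 to 6.71 ± 6.28 (-7.52 ± 0.73, adjusted p = 9.1e-10), and Enpep, a peptidase gene, from 889 ± 63.6 to the floor (adjusted p = 4.2e-12). In all, 2508 of 11412 tested genes differed, 1228 higher and 1280 lower, against 3260 with voom and 427 with a term for a break in library numbers described below. Upper quartile scaling gave 916 higher and 1484 lower. Leaving out 1 library at a time gave 1901 to 2265 genes, with 2265 without TUM replicate 1, which stood apart from replicates 2 and 3. In simulated data of this size 52 of 100 genes changed 2-fold and 89 of 100 changed 4-fold were called, with 7 false among 148 calls.

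Itgam, the gene of CD11b, rose in KEP tumors from 3695 ± 483 to 8129 ± 674 (1.14 ± 0.28, adjusted p = 0.0026), while Adgre1 (0.51 ± 0.23, adjusted p = 0.12) and the receptor gene Csf1r (-0.25 ± 0.17, adjusted p = 0.34) did not pass. Of 15 tested macrophage identity genes 5 rose and 0 fell (6 and 0 adjusted over the list alone; list adjusted p = 0.041), a call lost with an estimated correlation (adjusted p = 0.36). That call was also lost without WT replicate 3 (0.0757), TUM replicate 2 (0.0849) or TUM replicate 3 (0.127). Of 13 resident macrophage genes 0 rose and 10 fell (0 and 11 over the list alone; adjusted p = 7.6e-13), among them the lectin gene Clec10a (-6.58 ± 0.41), the chemokine gene Ccl24 (-5.90 ± 0.60) and the lectin gene Mgl2 (-5.70 ± 0.35). Both inflammatory monocyte genes that could be tested fell, too few for a list test. Of 18 tumor-macrophage literature genes 8 rose and 2 fell (8 and 2 over the list alone; adjusted p = 0.005, adjusted p = 0.11 with an estimated correlation), with Spp1 and the protease gene Mmp14 (69.1 ± 42.1 to 886 ± 114, 3.83 ± 0.56) in front.

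Glycolysis and hypoxia genes rose in KEP tumors, among them Vegfa, which drives vessel growth (217 ± 83 to 1893 ± 140.1, 3.19 ± 0.56, adjusted p = 4.2e-05), the glucose transporter gene Slc2a1 (98.1 ± 34.6 to 739 ± 145, 2.94 ± 0.33, adjusted p = 2.1e-08) and the glycolytic Pgam1 (2.27 ± 0.24) and Pgk1 (1.89 ± 0.23). Of 18 such genes 13 rose and 0 fell (15 and 0 adjusted over the list alone; adjusted p = 1.1e-10, 0.0091 with an estimated correlation). The cell cycle genes Cdk1, a mitotic kinase (3.08 ± 0.48, adjusted p = 7.3e-06), Ccnb1, its cyclin (3.02 ± 0.40, adjusted p = 4.1e-07), and Top2a, a DNA topoisomerase (112 ± 20.6 to 808 ± 245, 2.82 ± 0.28, adjusted p = 1.7e-09), rose with 16 of 17 listed genes (16 and 0 over the list alone; list adjusted p = 4.1e-16, 0.0091 with an estimated correlation). Cholesterol synthesis genes rose in 9 of 15 (9 and 0 over the list alone; adjusted p = 9.7e-06, 0.02 estimated), with the isomerase gene Idi1 at 2.08 ± 0.31, the demethylase gene Cyp51 at 1.72 ± 0.31 and the epoxidase gene Sqle at 1.32 ± 0.36. Immune checkpoint and suppression genes gave 4 higher and 1 lower of 10 (4 and 2 over the list alone; adjusted p = 0.0096, 0.026 estimated). Among them the signal-inhibiting receptor gene Sirpa rose by 1.36 ± 0.15 (adjusted p = 1.3e-08).

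Iron and heme genes fell in KEP tumors. Cd163, the hemoglobin scavenger receptor gene, went from 2779.6 ± 288 to 155 ± 107 (-4.56 ± 0.58, adjusted p = 1.8e-07), the transferrin receptor gene Tfrc from 1424 ± 157 to 164 ± 60.8 (-3.17 ± 0.42, adjusted p = 4.0e-07) and the secreted scavenger gene Cd5l from 240.0 ± 50.3 to 2.1 ± 2.25 (-6.50 ± 0.67, adjusted p = 3.4e-09). Of 12 listed genes 0 rose and 9 fell (0 and 9 adjusted over the list alone; adjusted p = 7.8e-08, 0.0012 with an estimated correlation). The immediate-early transcription factor genes Egr1 (13984 ± 4763 to 521 ± 329, -4.89 ± 0.47, adjusted p = 6.1e-10), Jun (8745 ± 4283 to 1784 ± 322, adjusted p = 6.6e-06) and Fos (-2.00 ± 0.42) and the phosphatase gene Dusp1 (-2.61 ± 0.40) fell with 10 of 17 genes of the immediate-early and dissociation response list (1 rose and 11 fell over the list alone; adjusted p = 6.1e-07, 0.022 estimated). In lipid uptake and efflux the scavenger receptor genes moved apart, Cd36 falling from 5212 ± 443 to 107 ± 63.7 (-5.83 ± 0.49, adjusted p = 3.3e-11) and Msr1 rising from 855 ± 162 to 7569 ± 3559.5 (3.05 ± 0.25, adjusted p = 2.8e-11). That list had 3 higher and 2 lower of 12 (adjusted p = 0.59). The lysosome list had 5 higher and 1 lower of 19 (adjusted p = 0.31), with the protease gene Ctss up by 1.21 ± 0.19 and the lipase gene Lipa down by 1.53 ± 0.19.

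Il6, a cytokine gene, fell in KEP tumors from 116 ± 61.9 to 4.37 ± 4.86 (-4.88 ± 0.94, adjusted p = 0.00016), and the interleukin-1 antagonist gene Il1rn rose from 804 ± 593 to 7070.1 ± 1581 (3.36 ± 0.48, adjusted p = 9.1e-06). The inflammatory cytokine and NF-kB list gave 5 higher and 2 lower of 21 (5 and 3 over the list alone; adjusted p = 0.92), and matrix proteases and inhibitors 6 higher and 2 lower of 15 (6 and 3 over the list alone; adjusted p = 0.16). The antiviral gene Oas2 fell by 2.36 ± 0.61 (adjusted p = 0.0043), a call lost without TUM replicate 3. Of 21 interferon-stimulated genes 0 rose and 6 fell (0 and 8 over the list alone; adjusted p = 0.0011, adjusted p = 0.42 with an estimated correlation), and the list was lost without TUM replicate 3 (0.278). MHC class II and co-stimulation genes gave 0 higher and 4 lower of 11 (0 and 5 over the list alone; adjusted p = 0.04, adjusted p = 0.42 with an estimated correlation). That list was lost without WT replicate 1 (0.106), WT replicate 2 (0.0595), TUM replicate 2 (0.0849) or TUM replicate 3 (0.371).

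Mammary epithelial transcripts, markers of other cells, were lower in KEP TUM mammary cells. Whether they came from epithelial cells in the sort was not tested. The milk protein gene Csn3 went from 382 ± 145 to 2.65 ± 2.54 (-6.98 ± 0.72, adjusted p = 6.6e-08), and the keratin genes Krt8 and Krt18 fell by 5.98 ± 0.95 (adjusted p = 1.0e-05) and 5.85 ± 0.73 (1.6e-07). All 8 tested epithelial genes fell (8 over the list alone; adjusted p = 1e-10, 0.0042 with an estimated correlation). Fibroblast genes were mixed, 1 higher and 4 lower of 11 (4 and 4 over the list alone; adjusted p = 0.61), with Dpt, a matrix protein gene, down by 3.21 ± 0.44. T and NK cell genes gave 0 higher and 3 lower of 8 (adjusted p = 0.04, adjusted p = 0.36 with an estimated correlation), lost without WT replicate 1 (0.0888), TUM replicate 2 (0.0776) or TUM replicate 3 (0.125). Dendritic cell genes gave 0 higher and 2 lower of 6 (adjusted p = 0.041, adjusted p = 0.12 with an estimated correlation), lost without WT replicate 1 (0.106), TUM replicate 2 (0.0561) or TUM replicate 3 (0.13). Siglech, a lectin gene of plasmacytoid cells, fell by 5.90 ± 0.58 (adjusted p = 7.9e-09). Neutrophil genes gave 0 higher and 2 lower of 6 (adjusted p = 0.14), B cell and plasma cell genes 0 and 1 of 7 (0.39), erythroid genes 0 and 1 of 10 (0.14) and endothelial genes 0 and 0 of 6 (0.15). The eosinophil, mast cell and adipocyte lists had 3, 3 and 1 tested genes, none called.

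**Figure D1:**
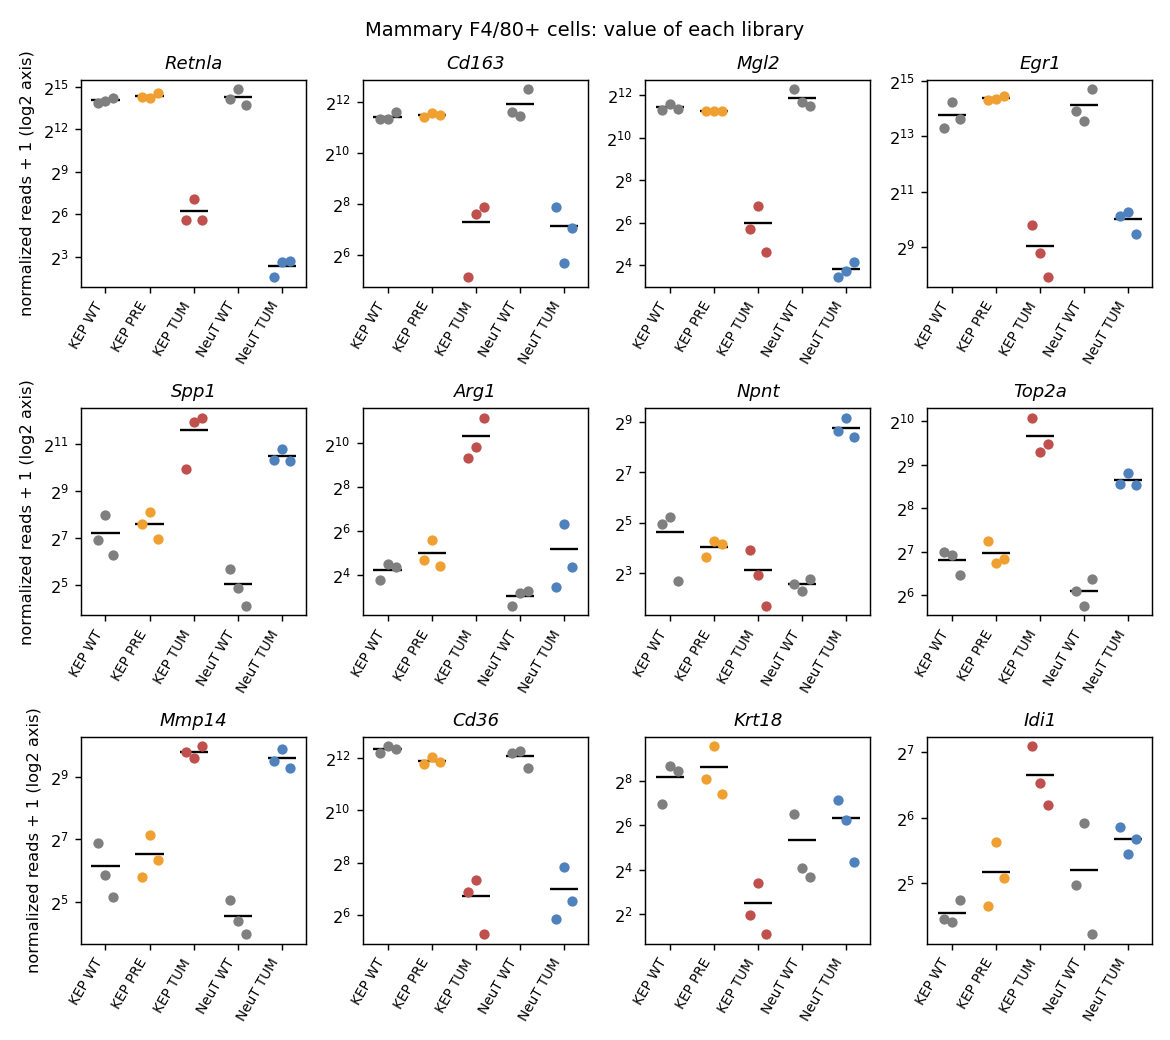
Normalized reads plus 1 on a log2 axis for 12 genes in mammary F4/80+ cells, 1 point per sample and a bar at the group mean, for KEP WT, PRE and TUM and NeuT WT and TUM (n = 3 each).

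In NeuT tumor macrophages Tmem119 rose from 5.84 ± 2.53 to 754 ± 53.8 (6.84 ± 0.65, adjusted p = 2.4e-10, n = 3 each). Galnt3, a glycosylation enzyme gene, rose from 2.51 ± 4.35 to 152 ± 31.7 (6.21 ± 0.50, adjusted p = 5.1e-12), and Npnt, a matrix ligand of integrins, from 4.93 ± 0.954 to 439 ± 123 (6.19 ± 0.49, adjusted p = 3.4e-12). The lectin receptor gene Klrb1b rose from 3.35 ± 5.8 to 169 ± 80.6 (6.15 ± 0.75, adjusted p = 5.2e-08), and Zmynd15, a transcriptional repressor gene, from 10.7 ± 5.11 to 645 ± 213 (5.84 ± 0.55, adjusted p = 1.8e-10). Cd276, a B7 family checkpoint gene, rose by 5.78 ± 0.70 (adjusted p = 4.1e-08) and Arhgap24 by 5.74 ± 0.55 (adjusted p = 2.4e-10). Serpine2, a protease inhibitor gene at the floor in WT, reached 275 ± 53.6 (adjusted p = 7.7e-12). Retnla fell from 20434 ± 8103 to 4.28 ± 2.01 (-11.93 ± 0.50, adjusted p = 9.1e-20), Cd209b from 3154 ± 733 to 8.94 ± 8.08 (-9.04 ± 0.86, adjusted p = 2.6e-10), and Mgl2 from 3673 ± 1128 to 13 ± 3.43 (-8.03 ± 0.35, adjusted p = 2.0e-19). Cd209d, Cd209f and the chemokine gene Cxcl12 changed by -8.91 ± 0.71, -8.46 ± 0.78 and -7.79 ± 0.71.

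In NeuT, 3158 of 11310 tested genes differed, 1588 higher and 1570 lower. Voom called 1921 and the compared groups alone 1443, and leaving out 1 library gave 2552 to 2913. In simulated data of this size 63 of 100 genes changed 2-fold and 94 of 100 changed 4-fold were called, with 33 false among 190 calls. That false share is above the adjusted p limit, and the share among the 3158 calls is not known. Adgre1 (0.23 ± 0.23, adjusted p = 0.5), Itgam (-0.60 ± 0.28, adjusted p = 0.11) and Csf1r (-0.33 ± 0.17, adjusted p = 0.16) were not called. Aif1, a cytoskeletal gene of macrophages, rose by 1.55 ± 0.29 (adjusted p = 6.8e-05) and Cd68, a lysosomal membrane gene, fell by 0.86 ± 0.19 (adjusted p = 0.00075).

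Every 1 of 15 resident macrophage genes fell in NeuT tumors (15 over the list alone; adjusted p = 5.2e-21, 9.3e-05 with an estimated correlation), among them the ficolin gene Fcna (2352 ± 589.5 to 42.2 ± 59, -6.97 ± 0.78). Of 18 tumor-macrophage literature genes 9 rose and 4 fell (11 and 4 over the list alone; adjusted p = 0.0035, adjusted p = 0.17 with an estimated correlation), led by Spp1 (31.3 ± 17.4 to 1441 ± 306, adjusted p = 1.9e-12), Mmp14 (5.08 ± 0.56) and the elastase gene Mmp12 (3.14 ± 0.72). Cell cycle genes rose in 19 of 22 (19 over the list alone; adjusted p = 9.3e-13, adjusted p = 0.10 with an estimated correlation), with the spindle gene Tpx2 at 3.51 ± 0.32 (2.4e-10) and the cyclin gene Ccna2 at 2.73 ± 0.30 (5.0e-09). Glycolysis and hypoxia genes gave 11 higher and 1 lower of 17 (adjusted p = 0.00051, adjusted p = 0.23 estimated), with Vegfa at 2.71 ± 0.56. Iron and heme genes gave 0 higher and 6 lower of 13 (adjusted p = 0.00064, adjusted p = 0.084 with an estimated correlation), with Cd163 at -4.99 ± 0.58, Tfrc at -4.27 ± 0.42 and the heme oxygenase gene Hmox1 at -2.35 ± 0.35. Immediate-early and dissociation genes gave 1 higher and 7 lower of 17 (adjusted p = 0.00044, adjusted p = 0.17 estimated), with Egr1 at -4.09 ± 0.47.

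The cytokine gene Il12b rose in NeuT tumors from 7.11 ± 6.9 to 307 ± 298 (5.52 ± 1.17, adjusted p = 0.00043), the chemokine gene Cxcl16 rose by 3.59 ± 0.61 (2.0e-05) and the neutrophil attractant gene Cxcl3 fell by 5.27 ± 0.65 (6.0e-08). Ctss rose from 3241 ± 460.2 to 15429 ± 2778 (2.25 ± 0.19, adjusted p = 3.0e-11), and Cd36 fell from 4269.6 ± 996 to 126 ± 92 (-5.28 ± 0.49, adjusted p = 1.5e-10). The inhibitory receptor gene Cd200r1 fell by 2.47 ± 0.32 (1.6e-07) and Il4ra, which encodes the interleukin-4 receptor, rose by 1.50 ± 0.34 (0.00075). Cholesterol synthesis genes gave 2 higher and 2 lower of 14 (adjusted p = 0.99), and interferon-stimulated genes 0 and 0 of 21. Mammary epithelial genes gave 2 higher and 0 lower of 9 (adjusted p = 0.10). Fibroblast genes gave 0 higher and 4 lower of 10 (0 and 6 over the list alone; adjusted p = 0.0075, adjusted p = 0.28 with an estimated correlation), with Dcn, a matrix proteoglycan gene, at -3.72 ± 0.65.

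KEP and NeuT tumor macrophages shared 1232 genes called in the same direction, among 10972 tested in both. Together 646 rose in both against 165.5 expected of independent lists, 586 fell in both against 162.4, and 72 went opposite ways against 328. Arhgap24, Spp1, Mmp14 and Tmem119 rose and Retnla, Cd209b, Cd209d, Clec10a, Ccl24 and Mgl2 fell in each model, which share no samples. The tests do share 1 estimate of spread per gene, which can raise the overlap above that of independent lists. The tumor changes correlated across genes at r = 0.55. The compared groups alone, with a separate spread for each model, gave 566 shared genes. Of these 285 rose in both against 56.9 expected, and 281 fell in both against 63.3. A term for the break in library numbers described below gave 280.0, and leaving out 1 library gave 931 to 1197.

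**Figure D2:**
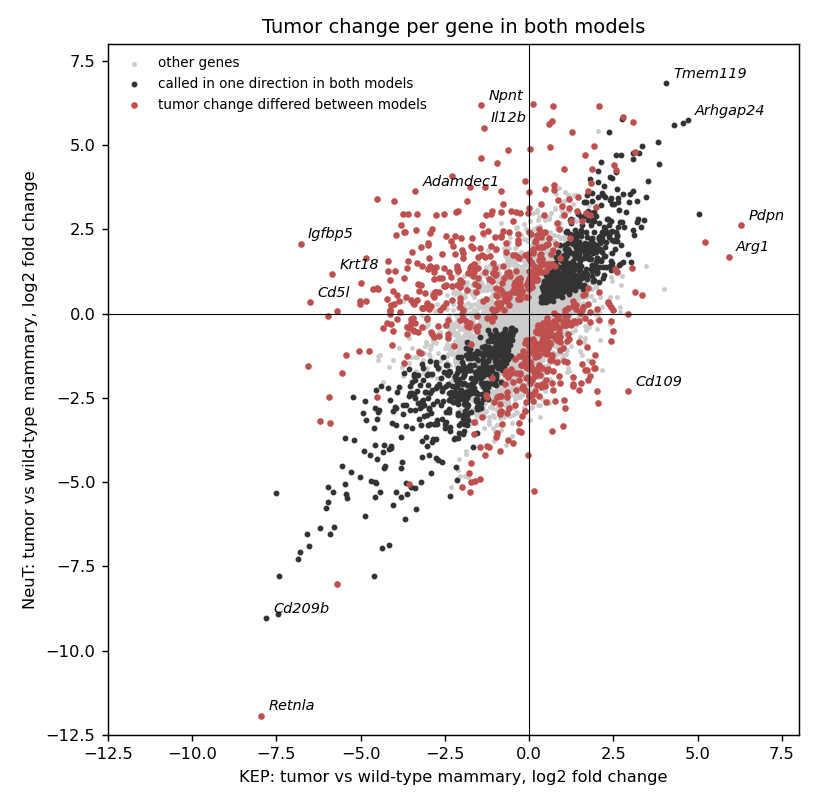
Log2 fold change of tumor-bearing against WT mammary F4/80+ cells per gene, KEP against NeuT. Black, called in the same direction in each model. Red, tumor change differing between the models.

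The tumor change of Arg1 was 4.23 ± 1.06 log2 units larger in KEP than in NeuT (adjusted p = 0.011), where Arg1 went from 7.22 ± 1.96 to 35.8 ± 37 (1.69 ± 0.75, adjusted p = 0.092). Pdpn rose in each model, by 6.28 in KEP and 2.62 ± 0.68 in NeuT (difference 3.66 ± 0.96, adjusted p = 0.016, and 0.0755 without KEP TUM replicate 3). The protease gene Mmp19, the lectin gene Clec4e and the membrane protein gene Cd109 rose in KEP (1.49 ± 0.47, 1.81 ± 0.49 and 2.93 ± 0.75) and fell in NeuT (-2.28 ± 0.47, -1.86 ± 0.49 and -2.31 ± 0.75). Retnla fell less in KEP (difference 3.99 ± 0.70, adjusted p = 0.00025). In the other direction Npnt fell in KEP by 1.43 ± 0.49 and rose in NeuT (difference -7.62 ± 0.69, adjusted p = 4.1e-09). The binding protein gene Igfbp5 (-8.86 ± 1.21, adjusted p = 5.0e-06), Krt18 (-7.01 ± 1.04, adjusted p = 2.0e-05) and Cd5l (-6.83 ± 0.95, adjusted p = 7.2e-06) fell in KEP alone by the call, and the protease gene Adamdec1 (-7.02 ± 1.19, adjusted p = 0.00015) fell in KEP and rose in NeuT. Il12b differed by -6.87 ± 1.66 (adjusted p = 0.008).

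This interaction was called for 703 of 10972 genes, 294 with the KEP change above the NeuT change and 409 below. It fell to 468 without KEP WT replicate 2, to 158 in the compared groups alone and to 85 with that term. Cholesterol synthesis genes were relatively higher in KEP, 5 higher and 0 lower of 14 (9 and 0 over the list alone; adjusted p = 1.6e-05, 0.035 with an estimated correlation). Mammary epithelial genes, markers of other cells, were relatively lower in KEP, 7 of 7 (adjusted p = 2.5e-14, 0.00034 estimated). Resident macrophage genes were relatively higher, 3 and 0 of 13 (7 and 0 over the list alone; adjusted p = 0.00032, adjusted p = 0.20 with an estimated correlation). NeuT libraries were shallower.

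Early-lesion KEP mammary macrophages differed little from WT. Dnajb1, a heat shock co-chaperone gene, rose from 867 ± 348 to 3145 ± 1374 (1.85 ± 0.25, adjusted p = 0.00011, n = 3 each), and stayed called without any 1 library, the highest adjusted p being 0.00506. Hexim1, an inhibitor of transcription elongation, rose from 217 ± 135 to 678 ± 292 (1.73 ± 0.29, adjusted p = 0.0023, and 0.111 without WT replicate 2). The matrix genes Dpt (17.1 ± 7.97 to 97.2 ± 37.7, 2.48 ± 0.44, adjusted p = 0.0039) and Col3a1 (35.7 ± 15.4 to 244 ± 74.2, 2.78 ± 0.59, adjusted p = 0.02) rose, at 0.111 and 0.273 without WT replicate 2. Lum, a proteoglycan gene, rose by 2.68 ± 0.56 (adjusted p = 0.02, and 0.284 without PRE replicate 2) and the collagen gene Col1a1 by 2.96 ± 0.68 (adjusted p = 0.031, kept in 1 of 6 leave-one-out runs). The cystine transporter gene Slc7a11 (2.29 ± 0.47, adjusted p = 0.02), the protease inhibitor gene Slpi (2.12 ± 0.47, 0.026), the coagulation factor gene F5 (2.06 ± 0.43, 0.02) and the growth arrest gene Gadd45a (1.86 ± 0.41, 0.026) were each lost in 3 or more runs. The only fall at a mean above 100 was Msantd4, a gene of little known role (-1.13 ± 0.26, adjusted p = 0.028).

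Fibroblast genes rose as a list in PRE mammary cells, 4 higher and 0 lower of 11 (9 and 1 adjusted over the list alone; adjusted p = 5.1e-16, 0.00021 with an estimated correlation). Matrix proteases and inhibitors had 0 called of 15 (3 and 0 over the list alone; adjusted p = 0.028, adjusted p = 0.42 with an estimated correlation), lost without WT replicate 3 (0.364), PRE replicate 1 (0.0988) or PRE replicate 2 (0.352). T and NK cell genes gave 0 higher and 1 lower of 9 (0 and 2 over the list alone; adjusted p = 0.0034, adjusted p = 0.42 with an estimated correlation), lost without PRE replicate 1 (0.0733). WT mammary libraries came before and PRE after the break in library numbers described below. Retnla, at 21455 ± 3054 in PRE, and the other resident macrophage genes gave 0 calls of 15. Altogether 43 of 11584 genes were called, 35 higher and 8 lower, with 706 at an unadjusted p below 0.05. The count was 8, 2 and 196 without WT replicates 1, 2 and 3, and 61, 7 and 25 without PRE replicates 1, 2 and 3. The compared groups alone called 0 genes, voom 178 and a term for the break 0 (limma, 310.0 unadjusted).

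Between early lesions and tumors of KEP Arg1 rose from 30.6 ± 14.6 to 1296 ± 899 (5.23 ± 0.75, adjusted p = 1.7e-06, n = 3 each) and Pdpn from 16.8 ± 9.47 to 793 ± 656 (5.08 ± 0.68, adjusted p = 5.1e-07). Retnla fell from 21455 ± 3054 to 76.6 ± 50.6 (-8.29 ± 0.50, adjusted p = 1.6e-14), Cd209d by 7.78 ± 0.71 (2.3e-10) and Egr1 from 21096 ± 1112 to 521 ± 329 (-5.53 ± 0.47, adjusted p = 3.0e-11). The matrix genes Dpt (-5.69 ± 0.44, adjusted p = 6.0e-12), Dcn (-4.53 ± 0.65, adjusted p = 1.6e-06) and Lum (-4.22 ± 0.56, adjusted p = 4.0e-07) fell. Havcr2, an inhibitory receptor gene, rose from 138 ± 28.3 to 689.9 ± 113 (2.32 ± 0.35, adjusted p = 3.2e-05).

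Of 11434 genes tested between PRE and TUM mammary cells 2844 differed, 1272 higher and 1572 lower, with 2183 to 2592 when 1 library was left out. TUM mice were 8 and PRE mice 4 months old, so stage and age cannot be told apart. Cell cycle genes gave 16 higher and 1 lower of 17 (adjusted p = 1.1e-14, 0.018 with an estimated correlation), with Ccna2 at 2.72 ± 0.30. Glycolysis and hypoxia genes gave 12 higher and 1 lower of 18 (13 and 1 over the list alone; adjusted p = 4.7e-08, 0.032 estimated), with Slc2a1 up from 169 ± 75.7 to 739 ± 145 (adjusted p = 4.0e-06). Checkpoint genes gave 6 higher and 2 lower of 11 (adjusted p = 0.0095, 0.032 estimated). Resident macrophage genes gave 0 and 10 of 13 (0 and 11 over the list alone; adjusted p = 3.4e-11, 0.0058 estimated), iron and heme genes 0 and 9 of 12 (1.2e-07, 0.0016 estimated), with Hmox1 at -2.91 ± 0.35, and immediate-early and dissociation genes 0 and 12 of 17 (2.3e-06, 0.032 estimated). Mammary epithelial genes fell in 8 of 8 (6.9e-10, 0.0071 estimated), with Krt18 at -6.18 ± 0.73. Cholesterol synthesis genes gave 8 higher and 1 lower of 14 (9 and 1 over the list alone; 0.00067, adjusted p = 0.071 estimated), and fibroblast genes 0 and 5 of 11 (0 and 6 over the list alone; 0.00029, adjusted p = 0.094 estimated). Interferon-stimulated genes gave 0 and 4 of 21 (0.0015, adjusted p = 0.49 estimated), lost without TUM replicate 3 (0.317).

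Thy1, a T cell surface gene, followed the library numbers of KEP rather than its groups. It lay between 420.2 and 1355 in the 14 libraries numbered up to PRE spleen replicate 2, and between 1.04 and 80.6 in the 13 after it, PRE spleen replicate 3 among them. The transcription factor gene Foxp2 (24.9 to 240.2 before, 1.64 to 6.51 after), the T cell receptor gene Cd3e (12.3 to 38.6 before, at the floor after) and the lectin receptor gene Klrg1 (10.7 to 35.9 before, 0.168 to 4.82 after) split likewise. Within each tissue 12 of 11201 genes were lower and 13 higher in every library after this break than in every library before it, Thy1, Cd8a, Gimap1, Il2rb and the ribosomal protein gene Rpl23 among them. With PRE spleen replicate 1 or 2 put in the place of replicate 3 the numbers were 0 and 0, and 1 and 0. All TUM libraries came after the break, all WT libraries and PRE marrow before it. Only TUM against PRE mammary cells, PRE against WT marrow and the WT tissues lay on 1 side. This check and the term for the break were chosen after the values were seen.

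The term for the break came from PRE spleen, which lies on both sides. It was taken as equal in log2 units in all KEP tissues. Thy1 is among the genes that placed the break, so its values with the term do not test the break. With the term Thy1 in TUM against WT went from -6.35 to 1.88 ± 1.24 in mammary cells, from -6.60 to 1.63 ± 1.24 in spleen and from -7.17 to 1.06 ± 1.24 in marrow (adjusted p = 0.56, 1 and 1). In KEP TUM against WT mammary cells 427 of 11327 genes were called, 175 higher and 252 lower. Pdpn (6.36 ± 1.25, adjusted p = 0.0018), Arg1 (5.79 ± 1.38, 0.011), Spp1 (5.32 ± 0.75, 2.9e-05), Retnla (-7.98 ± 0.91, 8.1e-07) and Egr1 (-5.97 ± 0.82, 2.1e-05) kept their calls. Calls were lost at similar fold changes and a larger SE for Itgam (1.33 ± 0.51, adjusted p = 0.17), Krt8 (-5.72 ± 1.75, 0.058), Erbb2 (-3.84 ± 1.21, 0.069) and Sqle (1.19 ± 0.66, 0.44). They were lost at smaller fold changes for Tmem119 (3.48 ± 1.18, 0.10), Cdk1 (2.41 ± 0.87, 0.14), Cyp51 (1.22 ± 0.56, 0.29), Cd163 (-2.60 ± 0.98, 0.16), Il6 (-1.84 ± 1.61, 0.72) and Oas2 (-0.79 ± 1.06, 0.86). The macrophage identity list (adjusted p = 0.109), the interferon-stimulated list (0.901) and the T and NK cell list (0.499) were also lost there.

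Elsewhere limma with the term called 0 genes in PRE against WT mammary cells (310.0 at unadjusted p below 0.05), TUM against WT spleen (374) and marrow (418), TUM against PRE spleen (295) and marrow (255), and the interactions in spleen (862) and marrow (511). Voom was not fitted with it. PRE against WT spleen gave 1 gene and the mammary interaction 85. The models shared 280.0. Dnajb1 in PRE mammary cells went to 1.32 ± 0.45 and Col3a1 to 4.15 ± 1.04 (adjusted p = 1 and 0.68). Cd93 and Colec12 in TUM spleen went to 0.93 ± 0.59 and 0.72 ± 0.48. In TUM marrow Rasgrp1 went to -2.34 ± 0.58 (adjusted p = 0.64) and Csf1r, at a like fold change, to -1.11 ± 0.32 (0.77). The T and NK cell list was lost in PRE mammary cells (0.196) and TUM spleen (0.767), and the lysosome list in TUM spleen (0.0696). The interferon-stimulated list was lost in TUM marrow (0.908) and the marrow interaction (0.621). The term rests on 3 libraries, of which 1 lies after the break, so a call lost with it does not show that a gene was unchanged.

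**Figure D3:**
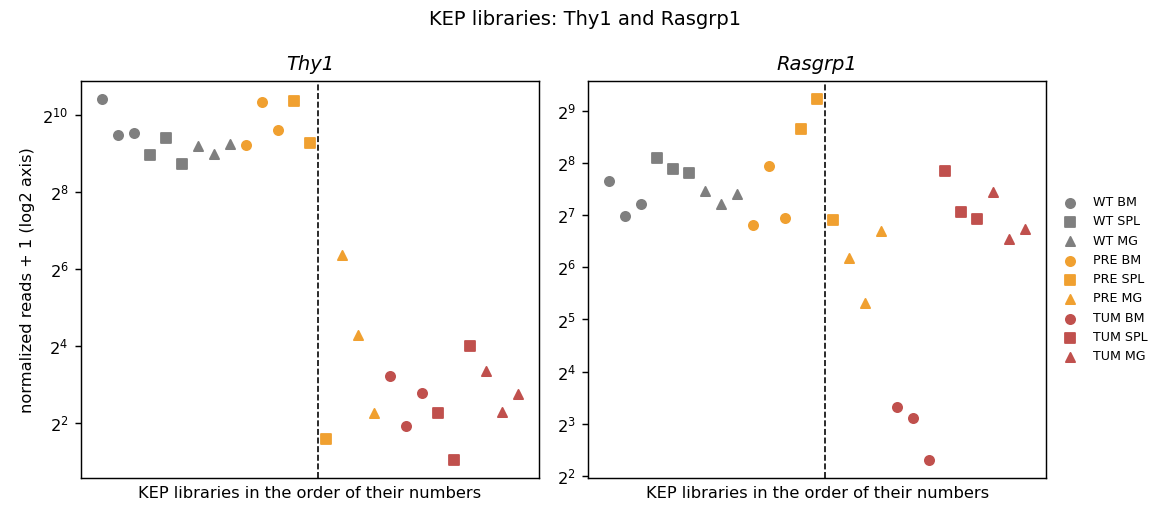
Normalized reads plus 1 on a log2 axis for Thy1 and Rasgrp1 in the 27 KEP samples, in the order of their library numbers, colored by stage and shaped by tissue. The dashed line marks the break between PRE spleen replicates 2 and 3.

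In the spleen of KEP tumor-bearing mice Cd93, a C1q-binding receptor gene, rose from 377 ± 27.3 to 1058 ± 199.8 (1.47 ± 0.33, adjusted p = 0.019, n = 3 each) and the scavenger receptor gene Colec12 from 59.2 ± 12.2 to 159 ± 9.96 (1.43 ± 0.28, adjusted p = 0.0084). Thy1 was at 528 ± 126 in WT and 6.55 ± 7.3 in TUM (-6.60 ± 1.29, adjusted p = 0.012), a difference that followed the library numbers, and the receptor gene Il18r1 fell by 2.23 ± 0.48 (0.016). Every 1 of these calls was lost without WT replicate 3, TUM replicate 1 or TUM replicate 2. Of 11880 genes 143 differed, 20 higher and 123 lower, around a median shift of -0.17. Quantile normalization gave 48 higher and 55 lower, and upper quartile scaling 48 and 56. The count was 455 and 0 without WT replicates 2 and 3, and 9, 11 and 218 without TUM replicates 1, 2 and 3. Voom called 664, the compared groups alone 5 and the term for the break 0 (limma, 374 unadjusted).

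T and NK cell genes, of which Cd3e and Cd8a followed the library numbers, were lower as a list in KEP TUM spleen, 0 higher and 3 lower of 8 (0 and 7 over the list alone; adjusted p = 1.6e-06, 0.029 with an estimated correlation), and so did B cell genes, 0 and 4 of 7 (0 and 7 over the list alone; adjusted p = 1.7e-06, 0.029 estimated). Lysosome genes moved up, 1 and 0 of 19 (7 and 0 over the list alone; adjusted p = 1.2e-08, 0.029 estimated), and lipid uptake and efflux genes had 0 called of 12 (4 and 0 over the list alone; adjusted p = 8.4e-06, 0.00085 estimated). Cell cycle genes moved down, 0 and 1 of 20 (0 and 13 over the list alone; adjusted p = 1.2e-08, adjusted p = 0.12 with an estimated correlation), with Top2a at -1.19 ± 0.28 (adjusted p = 0.03). These list calls held without any 1 library. PRE against WT spleen called 0 genes (350 at unadjusted p below 0.05; voom 0, with 560 unadjusted), and 1 gene without PRE replicate 3. TUM against PRE spleen called 6 of the tested genes, 1 higher and 5 lower, among them Colec12 (1.37 ± 0.28, adjusted p = 0.048) and the T cell co-receptor gene Cd8a (-2.20 ± 0.39, adjusted p = 0.048), around a median shift of -0.11. That count was 0 without PRE replicate 1, PRE replicate 2, TUM replicate 1 or TUM replicate 2, 27 without PRE replicate 3 and 42 without TUM replicate 3. Upper quartile scaling gave 1 higher and 2 lower. The term for the break gave 0 (limma, 295 unadjusted).

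NeuT tumor-bearing spleen (n = 2 against 3) showed Lipg, a lipase gene at the floor in WT, at 101 ± 66.8 (adjusted p = 0.00027), and the spindle gene Tpx2 up from 44.3 ± 19.7 to 165 ± 70 (1.91 ± 0.35, adjusted p = 0.0066). Blvrb, a biliverdin reductase gene, fell from 87.1 ± 28.3 to 26.2 ± 3.82 (-1.65 ± 0.32, adjusted p = 0.0066). Cdk1 rose by 2.60 ± 0.54 (0.0083) and the checkpoint kinase gene Bub1 by 2.26 ± 0.46 (0.0076), each lost without WT replicate 1 or TUM replicate 2. Tpx2 was lost without TUM replicate 2, while Lipg and Blvrb held in all 5 runs. Cell cycle genes gave 15 higher and 0 lower of 22 (18 and 0 over the list alone; adjusted p = 3.2e-23, 0.017 with an estimated correlation). Immediate-early genes gave 0 and 3 of 19 (adjusted p = 0.0017, adjusted p = 0.63 with an estimated correlation). Of 11874 genes 279 differed, 141 higher and 138 lower, and values as deposited gave 56 and 86. The count was 54, 528 and 431 without WT replicates 1, 2 and 3, and 230.0 and 71 without TUM replicates 1 and 2. Voom and the compared groups alone called 0.

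The spleen changes of the models differed in 386 of 11603 genes, 82 with KEP above NeuT and 304 below, around a median shift of -0.13. Cell cycle genes led the second direction, 0 and 14 of 20 (0 and 19 over the list alone; adjusted p = 5e-23, 0.011 with an estimated correlation). Cdk1 differed by -3.60 ± 0.72 (adjusted p = 0.0027), the spindle gene Nusap1 by -3.51 ± 0.62 (0.0012), Bub1 by -3.46 ± 0.61 (0.0012), the condensin gene Ncapd2 by -3.37 ± 0.64 (0.002), the replication gene Ticrr by -3.35 ± 0.60 (0.0012) and the condensin gene Ncapg by -3.28 ± 0.90 (0.036). In the first direction stood the membrane gene Emp1 (3.03 ± 0.70, 0.01), the GTPase gene Rras (2.32 ± 0.47, 0.0046), the receptor gene Nr4a1 (2.04 ± 0.51, 0.018) and the lipid carrier gene Apoe (2.00 ± 0.46, 0.01). Lipid uptake and efflux genes gave 1 and 0 of 12 (4 and 0 over the list alone; adjusted p = 0.00088, 0.012 estimated). Quantile normalization gave 127 above and 170 below, upper quartile scaling 135 and 210. The count fell to 150.0 without KEP WT replicate 3, 179 and 204 without KEP TUM replicates 1 and 2, 190.0 without NeuT WT replicate 1 and 172 without NeuT TUM replicate 2, and rose to 655 without NeuT WT replicate 3. The compared groups alone gave 1, and the term for the break 0 (limma, 862 unadjusted).

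In KEP bone marrow Rasgrp1, a Ras activator gene of lymphocytes, fell from 158 ± 38.9 to 6.82 ± 2.61 (-4.38 ± 0.40, adjusted p = 7.5e-08, n = 3 each), and Thy1, which followed the library numbers, from 935 ± 364 to 5.65 ± 2.79 (-7.17 ± 1.29, adjusted p = 0.0042). Csf1r fell from 1329 ± 146 to 632 ± 143 (-1.09 ± 0.17, adjusted p = 0.00061), Adgre1 from 237 ± 25.4 to 114 ± 16.7 (-1.06 ± 0.23, adjusted p = 0.013) and Ctss from 2112 ± 479 to 1003 ± 135 (-1.06 ± 0.19, adjusted p = 0.0025). Thy1, Rasgrp1, Csf1r and Ctss held without any 1 library, at adjusted p up to 4.61e-06 for Rasgrp1, 0.0111 for Csf1r and 0.0485 for Ctss. The heme synthesis gene Alas1 rose by 1.08 ± 0.24 (0.022). The neutrophil gene S100a8 held 1.68% to 3.31% of reads in WT marrow and 2.66% to 6.04% in TUM marrow. A change in the mix of sorted cells was not separated from a change of the macrophages. Macrophage identity genes gave 0 higher and 3 lower of 15 (0 and 3 over the list alone; adjusted p = 2.5e-05, adjusted p = 0.19 with an estimated correlation), and interferon-stimulated genes 0 and 1 of 21 (0 and 3 over the list alone; adjusted p = 3.4e-08, adjusted p = 0.21 with an estimated correlation). Of 11942 genes 127 differed, 23 higher and 104 lower, against 16 and 193 with quantile normalization, 14 and 193 with upper quartile scaling and 123 and 136 as deposited. The count was 38, 73 and 42 without WT replicates 1, 2 and 3 and 36 without TUM replicate 1. Voom called 327, the compared groups alone 9 and the term for the break 0 (limma, 418 unadjusted).

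Thy1 stayed at 883 ± 356 in PRE marrow and fell to 5.65 ± 2.79 in TUM (-7.08 ± 1.29, adjusted p = 0.02), a call lost in all 6 leave-one-out runs, with the highest adjusted p of 0.237 without PRE replicate 2. Rasgrp1 fell from 159 ± 73.7 in PRE (-4.33 ± 0.40, adjusted p = 1.0e-07) and held in all 6. Cd8a, at the floor in TUM marrow, and Ctss (-0.90 ± 0.19, adjusted p = 0.041) were also lower than in PRE. All PRE marrow libraries came before the break in library numbers and all TUM after it. These were among 14 genes, 1 higher and 13 lower (10 and 15 as deposited), and the count was 5, 1 and 7 without PRE replicates 1, 2 and 3 2, 3 and 3 without TUM replicates 1, 2 and 3, and 0 with the term for the break (limma, 255 unadjusted). Erythroid genes had 0 called of 10 (8 and 0 over the list alone, median 3.10; adjusted p = 4.2e-11, 0.022 with an estimated correlation). PRE against WT marrow called 0 genes (182 at unadjusted p below 0.05; voom 0, with 315 unadjusted; 2 as deposited). Lists nevertheless moved down there, macrophage identity (0 of 15 called, 0 and 5 over the list alone; adjusted p = 6.5e-11, 0.0012 estimated), resident macrophage (0 of 13; 1.8e-13, 0.0012 estimated), lipid uptake and efflux (0.002, 0.023 estimated), immediate-early (2e-09, 0.011 estimated) and erythroid genes (3.3e-10, 0.011 estimated). The erythroid call was lost without WT replicate 1 (0.0685).

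NeuT tumor-bearing bone marrow had more Camk2d, a calcium-dependent kinase gene (60 ± 24.2 to 172 ± 8.86, 1.57 ± 0.25, adjusted p = 0.0011, n = 3 each), and less Timp2, a protease inhibitor gene (327 ± 79.6 to 95.5 ± 62.1, -1.92 ± 0.31, adjusted p = 0.0011). Apoe fell from 714 ± 3.82 to 214 ± 69.4 (-1.78 ± 0.31, adjusted p = 0.0025) and Cd36 from 29.2 ± 14 to 1.2 ± 1.04 (-3.80 ± 0.49, adjusted p = 4.4e-05), and these 4 genes held without any 1 library. Macrophage identity genes gave 0 higher and 3 lower of 14 (0 and 8 over the list alone; adjusted p = 1.9e-06, 0.025 with an estimated correlation), matrix genes 0 and 3 of 15 (1 and 6 over the list alone; 6.9e-05, 0.025 estimated) and iron and heme genes 0 and 1 of 12 (1 and 5 over the list alone; 0.00051, 0.047 estimated). Of 11823 genes 58 differed, 32 higher and 26 lower, against 27 and 36 with upper quartile scaling and 29 and 54 as deposited. The count was 17, 17 and 584 without WT replicates 1, 2 and 3, and 12 and 18 without TUM replicates 1 and 2. Voom called 6 and the compared groups alone 0.

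The marrow changes of the models differed for 27 of 11605 genes, 5 with KEP above NeuT and 22 below. P2rx7, an ATP-gated channel gene, fell in KEP by 1.09 ± 0.20 and did not in NeuT (0.78 ± 0.20, difference -1.86 ± 0.28, adjusted p = 0.0013), held in all 12 runs. The protease inhibitor gene Stfa3 differed by 4.48 ± 0.92 (adjusted p = 0.04), the interferon-inducible genes Parp12 by -2.14 ± 0.48 (0.047), Ifi203 by -1.89 ± 0.44 (0.049) and Mndal by -1.85 ± 0.42 (0.049), Camk2d by -1.86 ± 0.36 (0.022) and the actin regulator gene Ccdc88a by -1.71 ± 0.36 (0.04). Interferon-stimulated genes had 0 called of 17 (adjusted p = 6.1e-05, adjusted p = 0.69 with an estimated correlation). The count was 4, 15 and 1 without KEP WT replicates 1, 2 and 3, 5 and 1 without KEP TUM replicates 1 and 2, 3, 7 and 329 without NeuT WT replicates 1, 2 and 3, and 6, 10 and 54 without NeuT TUM replicates 1, 2 and 3. Quantile normalization called 7 above and 80 below, values as deposited 53 and 51, and the term for the break 0 (limma, 511 unadjusted).

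**Figure D4:**
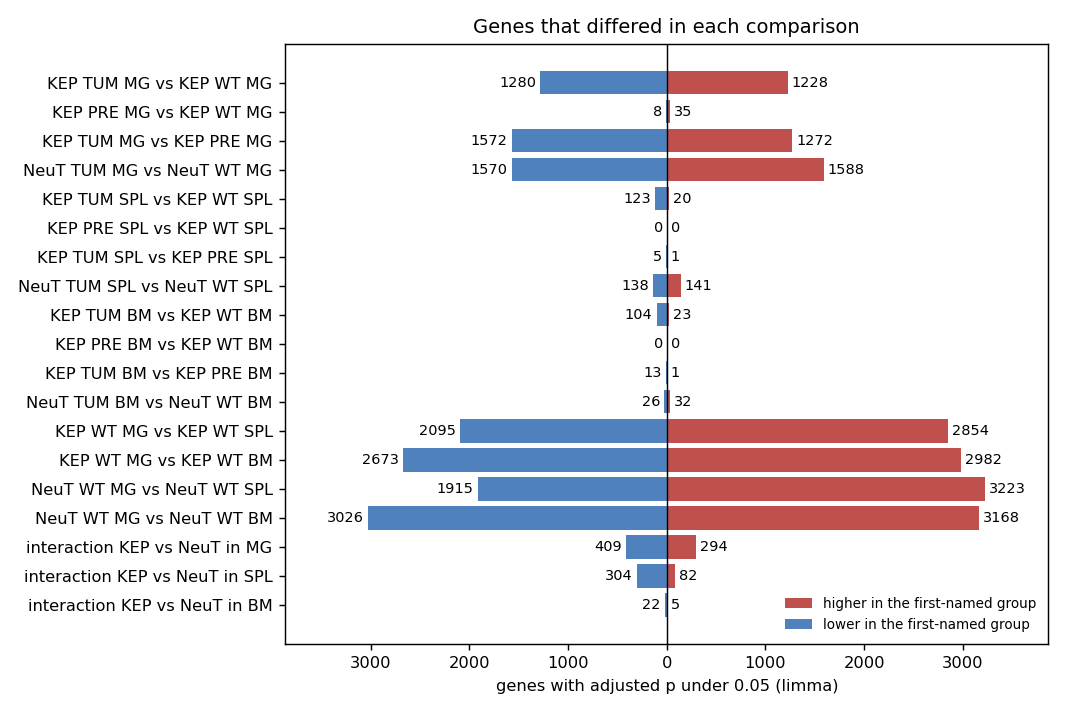
Genes called per comparison, red for higher and blue for lower in the first-named group, and for interactions the KEP change above or below the NeuT change.

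WT mammary macrophages carried far more Folr2, a folate receptor gene of tissue macrophages, than WT spleen cells in KEP (1838 ± 172 against 3.52 ± 1.09, 8.69 ± 0.58, adjusted p = 2.1e-14, n = 3 each). The chemokine gene Ccl7 (8.51 ± 0.64, adjusted p = 2.7e-13), the scavenger receptor gene Stab1 (8.49 ± 0.50, 7.9e-16), the complement gene C1qa (5.68 ± 0.39, 5.0e-14) and the growth factor gene Gas6 (7.92 ± 0.51, 7.6e-15) were also higher. Lower were S100a8, a granule protein gene of neutrophils (609 ± 263 against 40286 ± 20612, -5.95 ± 0.47, adjusted p = 1.2e-10), the collagenase gene Mmp8 (-6.43 ± 0.48, 1.7e-12) and the B cell gene Ms4a1 (-5.91 ± 0.59, 2.8e-10). Egr1 stood at 13984 ± 4763 against 229 ± 59.7 (5.91 ± 0.47, adjusted p = 1.0e-12), and Jun and the stress gene Atf3 were higher by 5.49 ± 0.34 and 6.66 ± 0.37. Mammary tissue alone was digested at 37 °C according to the labels, so tissue and preparation cannot be separated here. Of 11491 genes 4949 differed, 2854 higher and 2095 lower, and quantile and upper quartile scaling reversed the balance at 2527 and 3046, and 2364 and 2978, with median shifts of -0.11 and -0.14.

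Resident macrophage genes were higher in KEP WT mammary cells than in spleen in 13 of 13 (adjusted p = 6.3e-16, 0.00029 with an estimated correlation), immediate-early genes in 17 of 17 (1.9e-15, 0.00029 estimated), lysosome genes in 17 of 19 (6.9e-12, 0.0087 estimated) and cytokine genes in 18 of 20 (1.4e-10, 0.044 estimated). Cell cycle genes gave 1 higher and 15 lower of 17 (5.5e-12, 0.035 estimated), with the motor gene Kif11 at -3.95 ± 0.29, and B cell genes 0 and 7 of 7 (2.9e-06, 0.021 estimated). Against KEP WT bone marrow 5655 of 11492 genes differed, 2982 higher and 2673 lower. Retnla was higher by 7.63 ± 0.50 (adjusted p = 5.1e-15), Cd36 by 6.92 ± 0.49 (4.5e-14) and the cathepsin gene Ctsb by 3.37 ± 0.16 (6.6e-18), while the granule genes Elane (-7.35 ± 0.79, 1.0e-09) and Mpo (-7.25 ± 0.89, 1.7e-08) were lower. Resident macrophage genes were higher in 13 of 13 (5.2e-14, 0.0012 estimated), immediate-early genes in 18 of 18 (1.3e-17, 0.00014 estimated), cytokine genes in 20 of 20 (1.3e-12, 0.019 estimated), and cell cycle genes lower in 16 of 17 (1.3e-16, 0.0079 estimated).

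In NeuT WT mice Folr2 stood at 2917 ± 460.1 in mammary cells, 2.06 ± 1.81 in spleen (10.15 ± 0.58, adjusted p = 5.8e-16) and 3.53 ± 0.796 in marrow (9.34 ± 0.58, adjusted p = 1.3e-15, n = 3 each). The platelet factor gene Pf4 was higher by 10.38 ± 0.77 than in spleen and by 10.57 ± 0.77 than in marrow. The granule gene Ctsg was listed at 0 in mammary cells against 1087 ± 49.8 in marrow (adjusted p = 6.6e-14). Resident macrophage genes were higher in 15 of 15 against spleen (7.4e-17, 0.00086 with an estimated correlation) and marrow (1.6e-15, 0.001 estimated), and immediate-early genes in 15 of 18 (2.6e-09, 0.016 estimated) and 17 of 18 (1.4e-14, 0.001 estimated). Cell cycle genes gave 2 higher and 15 lower of 22 against spleen (1.4e-05, adjusted p = 0.25 with an estimated correlation) and 0 and 21 of 22 against marrow (6.8e-19, 0.017 estimated). Against spleen 5138 of 11397 genes differed, 3223 higher and 1915 lower around a median shift of 0.17, with 2535 and 2673 by quantile normalization, 2644 and 2709 by upper quartile scaling and 2823 in the compared groups alone. Against marrow 6194 of 11355 differed, 3168 higher and 3026 lower.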

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

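The tests of this part were chosen before their results were seen, except a term for a break in the library numbers, and each result below is a tumor change that differed between KEP and NeuT by the interaction test.

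In mammary cells 703 genes differed, led by Cd109 (5.24), Arg1 (4.23), Retnla (3.99), Mmp19 (3.77), Clec4e (3.67) and Pdpn (3.66) with the KEP change above, and by Igfbp5 (-8.86), Npnt (-7.62), Adamdec1 (-7.02), Krt18 (-7.01), Il12b (-6.87) and Cd5l (-6.83) below. The shallower NeuT libraries could add or remove such calls, so KEP reads were thinned to 1273390 per library over 10730 genes. The 10 draws called 441 to 511 genes against 677 unthinned, 405 to 453 of them also called unthinned. Depth thus moved the count, but how much of it depth made is not decided. Of 100 splits of the samples, with the tumor change common to the models removed first, the real one alone gave 716 genes, the highest other giving 463. The common change was removed by the real labels, so the splits do not show how much of the count the models made. Model, strain and library series separate every KEP from every NeuT sample, so cannot be told apart. Nor can age (8 months in KEP TUM, 4 in NeuT TUM). KEP WT and TUM libraries also lie on 2 sides of that break, and no biological explanation could be tested. With the term 85 genes were called, of those named only Cd109, Igfbp5, Npnt, Adamdec1 and Cd5l.

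The lists that differed in mammary cells were cholesterol synthesis (adjusted p = 0.0352 with an estimated correlation, relatively higher in KEP) and mammary epithelium (0.000338, relatively lower in KEP). In spleen 386 genes differed, with Emp1 (3.03), Rras (2.32), Nr4a1 (2.04), Clec4a1, a lectin receptor gene (2.01), Stxbp6, a vesicle fusion gene (2.01), and Apoe (2.00) above. Below stood the cell division genes Cdk1 (-3.60), Nusap1 (-3.51), Bub1 (-3.46), Ncapd2 (-3.37), Ticrr (-3.35) and Ncapg (-3.28). The spleen lists were cell cycle (adjusted p = 0.0106) and lipid uptake and efflux (0.0118), and NeuT tumor-bearing spleen had 2 samples, so no splits were counted there. In bone marrow 27 genes differed, with Stfa3 (4.48) above and Parp12 (-2.14), Ifi203 (-1.89), Camk2d (-1.86), P2rx7 (-1.86), Mndal (-1.85) and Ccdc88a (-1.71) below. There 3 of 100 splits gave 27 or more genes, the highest other giving 85, a share under 0.05. A split that calls 85 points to a structure of the samples, and the marrow count fell to 1 without KEP WT replicate 3 or KEP TUM replicate 2 and rose to 329 without NeuT WT replicate 3. With the term for the break limma called 0 genes in spleen (862 unadjusted) and marrow (511), and voom was not fitted with it.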

How the results depend on the processing

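The values as deposited, floored values at their upper limit, genes with values in all libraries, voom and the term for a break in library numbers were chosen after the data were seen, and the other settings before. KEP TUM against WT (2508 genes), TUM against PRE (2844) and the KEP WT tissue comparisons stayed within 1.5 times under every setting, apart from 427 for TUM against WT with the term for the break, with 1901 to 2265, 2183 to 2592, 4255 to 4599 (spleen) and 4914 to 5246 (marrow) genes when 1 library was left out. Leaving out 1 library gave 2552 to 2913 genes in NeuT TUM against WT, 931 to 1197 shared genes, and 4561 to 4948 and 5510 to 6130 for NeuT WT mammary cells against spleen and marrow. Small counts in spleen, marrow and PRE were not steady, and the cause was not tested.

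The compared groups alone, with fewer samples to estimate the spread, gave 0 genes for PRE against WT mammary cells (43 with all libraries, unadjusted 706, voom 178), 1443 for NeuT TUM mammary cells (3158), 5 for KEP TUM against WT spleen (143), 3 for TUM against PRE spleen (6), 0 for NeuT spleen (279), 9 for KEP TUM against WT marrow (127), 1 for TUM against PRE marrow (14), 0 for NeuT marrow (58), 2823 for NeuT WT mammary cells against spleen (5138), 158, 1 and 3 for the interactions in mammary cells, spleen and marrow (703, 386 and 27) and 566 shared genes (1232). A filter of 50, no filter, a pseudocount of 0.1, quantile normalization and genes with values in all libraries each gave 0 genes for TUM against PRE spleen by limma, against 17 by voom. Genes with values in all libraries, which are fewer, also gave 87 for KEP TUM against WT spleen and 1 for TUM against PRE marrow. Floored values at their upper limit gave 292 for KEP TUM against WT spleen, 15 for TUM against PRE spleen, 102 for NeuT marrow and 87 for the marrow interaction. A pseudocount of 0.1 gave 114 for NeuT marrow. A pseudocount of 10 gave 121 for PRE against WT mammary cells, 311 for KEP TUM against WT spleen, 4 for TUM against PRE marrow, 36 for NeuT marrow and 17 for the marrow interaction. Quantile normalization gave 92 for PRE against WT mammary cells, 209 for KEP TUM against WT marrow and 87 for the marrow interaction, and upper quartile scaling 3 for TUM against PRE spleen, 207 for KEP TUM against WT marrow and 47 for the marrow interaction.

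Values as deposited, which keep the constants, gave 134 for PRE against WT mammary cells, 689 for KEP TUM against WT spleen, 50 for TUM against PRE spleen, 142 for NeuT spleen, 259 for KEP TUM against WT marrow, 2 for PRE against WT marrow (0), 25 for TUM against PRE marrow, and 1540 and 104 for the interactions in mammary cells and marrow. Voom gave 178 for PRE against WT mammary cells, 1921 for NeuT TUM mammary cells, 664 for KEP TUM against WT spleen, 17 for TUM against PRE spleen, 0 for NeuT spleen, 327 for KEP TUM against WT marrow, 2 for TUM against PRE marrow, 6 for NeuT marrow, and 100 and 13 for the interactions in spleen and marrow.

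The term for the break, which PRE spleen alone gives and which enlarges the SE, gave 85 genes in the mammary interaction, 280.0 shared genes and 1 in PRE against WT spleen. By limma it gave 0 in PRE against WT mammary cells and in the spleen and marrow comparisons listed above (255 to 862 unadjusted). With it the change turned upward for Thy1 in TUM against WT mammary cells (1.88), spleen (1.63) and marrow (1.06) and in TUM against PRE marrow (1.15), for Cd3e in TUM against WT mammary cells (0.86), spleen (0.23) and marrow (0.31), and for Rtp4 in TUM against WT mammary cells (0.15), none of them called. Thy1 and Cd3e are among the genes that split at the break, so their turn does not test it. Cd3e was at the floor in all 13 libraries after the break, so its values with the term only compare PRE spleen replicates 1 and 2 with WT. Lists turned at these adjusted p, interferon-stimulated genes in TUM against WT mammary cells (0.901) and marrow (0.908), PRE against WT mammary cells (4.4e-07), TUM against PRE marrow (0.00844) and the mammary interaction (0.755). T and NK cell genes did in TUM against WT mammary cells (0.499) and marrow (0.377), PRE against WT mammary cells (0.196) and TUM against PRE marrow (0.043), and cytokine genes in TUM against WT spleen (0.0238) and marrow (0.95) and TUM against PRE spleen (0.027). Lysosome genes did in PRE against WT mammary cells (0.00907), resident macrophage genes in TUM against WT spleen (0.035) and immediate-early genes in TUM against PRE marrow (0.0307).

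Leaving out 1 library gave 2 to 196 genes for PRE against WT mammary cells, 0 to 455 for KEP TUM against WT spleen, 0 to 1 for PRE against WT spleen, 0 to 42 for TUM against PRE spleen, 54 to 528 for NeuT spleen, 36 to 123 for KEP TUM against WT marrow, 0 to 0 for PRE against WT marrow, 1 to 7 for TUM against PRE marrow, 12 to 584 for NeuT marrow, and 468 to 955, 150.0 to 655 and 1 to 329 for the interactions in mammary cells, spleen and marrow. Where it left 1 NeuT spleen sample, that sample is assumed to vary like the other groups. Apart from the term, the direction of a list turned in 4 cases. Immediate-early genes in PRE against WT mammary cells gave adjusted p = 0.0168 without KEP WT replicate 2 (0.0168 to 0.947 over the libraries), interferon-stimulated genes in PRE against WT spleen 0.0259 without PRE replicate 2 (0.000221 to 0.419) and cell cycle genes there 0.042 without WT replicate 3 (2.8e-07 to 0.864). The erythroid list of the marrow interaction gave 0.959 as deposited (main value 0.0212). Apart from all of these, settings other than left-out libraries left the outcome of a list, called or not called, as it was in 5168 cases, lost a call in 270.0 and gained one in 102, and for named genes in 8158, 709 and 11. With left-out libraries these were 2775, 120.0 and 92 for lists and 4149, 588 and 4 for named genes.

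No paired analysis was possible because the labels give no replicate numbers. The count-based tests named beforehand were not run, since the table holds no counts as deposited and the reads come from constants fitted here. At the depth of a NeuT library 1 read stood for 0.88 to 2.79 normalized reads, against 0.217 to 1.14 in KEP, so low values are coarser there.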

Other observations

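The genes shared by tissues or models in this part and the tests of Thy1 between TUM and PRE and of a break in the library numbers, with the term for it, were chosen after their values were seen.

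Among genes called in each model, Scd2, a fatty acid desaturase gene, rose in tumor macrophages by 3.13 ± 0.30 in KEP (adjusted p = 6.3e-10) and 4.81 in NeuT (1.3e-14). The integrin genes Itgav (3.08 ± 0.25 and 3.65) and Itga6 (3.07 ± 0.43 and 4.76), the guanine exchange factor gene Dock4 (2.99 ± 0.28 and 3.54) and the matrix gene Olfml3 (3.27 ± 0.72 and 4.77) also rose. The phospholipase gene Pla2g2d fell by 6.87 ± 0.58 in KEP (adjusted p = 3.1e-11) and 7.28 in NeuT (3.8e-12), with Mamdc2, a matrix proteoglycan gene (-6.80 ± 0.49 and -7.07), the receptor gene Gfra2 (-6.53 ± 0.53 and -6.88) and Timd4, a phosphatidylserine receptor gene (-5.41 ± 0.48 and -5.48). Of 100 combinations of a KEP split with a NeuT split, the real one alone gave 1232 shared genes, the highest other giving 24. Other splits of 1 model called at most 46 genes in KEP and 111 in NeuT, so few shared genes were possible there. The splits thus do not show that the changes are shared.

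In KEP tumor-bearing mice 8 of 11232 genes fell in bone marrow, spleen and mammary cells alike, against 0.112 expected of independent lists. The tests share 1 estimate of spread per gene, so the lists are not independent. The 8 genes were Thy1, the T and NK cell genes Cd3e, Cd8a, Il2rb (-3.76, -2.53 and -3.02 in the 3 tissues), Klrg1 (-3.50, -2.45 and -2.74) and Gimap1 (-2.51, -2.55 and -3.57), the Notch pathway gene Dtx1 and the transcription factor gene Foxp2 (-4.45, -3.63 and -4.57). The number of shared falls was 0 without WT spleen replicate 3 or TUM spleen replicate 2, 1 without TUM spleen replicate 1, 4 without WT marrow replicate 1 or WT spleen replicate 1, 5 without TUM marrow replicate 1, and 6 to 8 without any other library.

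The falls of Thy1 and these T cell genes may come from a break in the library numbers rather than from the tumor. PRE spleen replicate 3, numbered after the break, lay below replicates 1 and 2 in 7 of the 8 genes (Thy1 1.99 against 1314 and 611). The break was placed after such values were seen, so this is no independent test of it. With a term for the break Thy1 in TUM against WT was not called in any tissue. That term is the same PRE spleen difference in every tissue, so for Thy1 the loss of the call followed from the placing of the break. A break between WT and all later libraries is argued against in marrow, where PRE stood with WT at 883 ± 356 and TUM differed from PRE by -7.08, a call lost in all 6 leave-one-out runs, with adjusted p up to 0.237. In mammary cells PRE (34.2 ± 40.8) stood near TUM (6.24 ± 2.65, a difference of -1.50 ± 1.29), so there neither placing of the break is excluded. RNA of T cells, which the F4/80 sort should remove, may be what the earlier libraries carried, since medians of 12 further T cell genes in TUM against WT fell in spleen (-1.51), mammary cells (-1.12) and marrow (-0.80), but in mammary cells the median was -0.46 across the break in PRE against WT (0 called by limma) and -0.60 on 1 side of it in TUM against PRE (2 called), Cd3e lay at only 25.6 to 32.0 in WT marrow (its ratio to Thy1 in T cells was not measured) and Cd3d at 60.6 to 105 in WT and 51.2 to 232 in TUM. NeuT libraries have no part in this KEP break. Their medians of the further T cell genes in TUM against WT were -1.26 in mammary cells (3 of 11 called lower), -0.38 in spleen and -0.39 in marrow (0 called by limma in each). A loss of T cells with the tumor stays open in all 3 tissues of KEP, where TUM and WT lie on different sides of the break, though in mammary cells Thy1 was already low in PRE.

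In PRE mammary cells the collagen genes and Dnajb1 were higher than in WT. RNA of fibroblasts in the sort may explain the collagen genes, since the median of 12 further fibroblast genes rose by 1.36 (quartiles 0.59 and 2.18), 11 of them above 0 and 0 called by limma. Col3a1 reached 244 ± 74.2 and Dpt 97.2 ± 37.7 in PRE, and the sort for F4/80 should remove fibroblasts. Handling stress could raise heat shock genes, but the median of 16 further ones was 0.32 (quartiles 0.06 and 0.66), between the bounds set beforehand, and does not decide. A change of the macrophages with the early lesion, and the break in library numbers between WT and PRE, stay open, and with a term for the break limma called 0 genes there (310.0 unadjusted), Col3a1 standing at 4.15 ± 1.04.

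Comparisons of 3 against 3 samples have 10 splits, so no share under 0.05 is possible. In TUM against WT mammary cells 1 split, the real one, gave 2508 genes in KEP and 3158 in NeuT, the highest others giving 46 and 111. TUM against PRE mammary cells gave 2844 and at most 5 elsewhere. For PRE against WT mammary cells 2 splits gave 43 or more genes, the highest other 116, and for NeuT marrow 2 gave 58 or more, the highest other 84, which points to a structure of the samples. KEP TUM against WT gave 143 genes in spleen (others up to 106) and 127 in marrow (up to 1), and TUM against PRE 6 in spleen (up to 1) and 14 in marrow (0). PRE against WT called 0 genes by limma in spleen and marrow (350 and 182 unadjusted, voom 0), so all 10 splits gave as many, at most 44 and 0. WT mammary cells against spleen and marrow gave 4949 and 5655 genes in KEP (others up to 1 and 0) and 5138 and 6194 in NeuT (others up to 383 and 614).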
